A study of Mus musculus with 9 samples.

How the data were processed

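The deposited table held counts, whole reads assigned to genes for 9 libraries, which the authors made by trimming with Trim Galore 0.6.5, aligning with STAR 2.7.6a to GRCm38 and counting with featureCounts 1.6.3, per the submitters' processing notes. The annotation release, strandedness and handling of reads that map to several places are not given in the sources used here, so levels of genes that share reads with close relatives (Klra receptors, receptor segments, H2 genes) are uncertain. Coordinates in the table were compared with a GRCm38 annotation: of 49200 genes named in both, 49198 lay on the same chromosome and 1352 (2.75%) had the same start and end, so coordinates are given as the file's own and the build behind them is not known. Of the gene names, 1606 were Ensembl identifiers. RNA was extracted with TRIzol, with a column clean-up for small samples, selected with poly-T beads and read as 150 bp pairs on a NovaSeq, per the labels' protocols. No molecular identifiers are described there, so reads may include copies made by PCR.

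All 9 libraries entered 1 fit. Genes were kept with edgeR's filterByExpr (15292 of 56860), library sizes were scaled with TMM factors (0.928 to 1.05), and differences were tested with edgeR's quasi-likelihood F test (edgeR 4.0.16, limma 3.58.1, R 4.3.3), with robust dispersion estimates, 6 residual degrees of freedom and no block. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all tested genes of a comparison. The standard error of a log2 fold change was its size divided by the square root of F. Levels are the mean and SD of TMM-scaled CPM over 3 libraries, and a fold is 2 raised to the log2 fold change of the fit. The 3 comparisons were SiaLo_PD1pos against SiaHi_PD1pos, SiaHi_PD1pos against SiaHi_PD1neg, and SiaLo_PD1pos against SiaHi_PD1neg. They share libraries and are not independent.

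Before the files were read, 20 lists of genes for T cell states, sialylation, glycosylation, cell division and metabolism and 11 lists of markers of other cell types were fixed from general knowledge. Lists with at least 3 tested members were tested with camera (preset correlation 0.01), adjusted within the 20 and within the 11, and again with the correlation estimated from the data and with fry. Camera compares a list with all other genes, while fry asks whether its genes move on balance one way. Counts adjusted over the list alone used only the p-values of that list's members. Listed genes absent from the table under the names used were Znf683, Ddx58, Tcrg-C1, Tcrg-C2, Tcrg-C4, Cd163l1 and Ahsp.

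The genes named in the report followed a rule written before the files were read. It took Pdcd1, St6gal1, Cd8a, Cd8b1, Cd3e and Cd4, and for each comparison the 8 genes with the highest and the 8 with the lowest log2 fold change among those called, without overlap between the 3 libraries of each group, and with a mean of at least 5 CPM, leaving out gene models, ribosomal pseudogenes and receptor segments. It added up to 3 members of each list with the smallest adjusted p (1 where none passed) and the most abundant member of each marker list. Where a list had no called member it is given as counts only, and some genes that the rule names are not reported here. Slamf6, Ccr7, Il7r, Itga1, Klri2, Klra7, Tyr and the T cell core genes were chosen after their values were seen.

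Alternatives fixed before the files were read were DESeq2's size factors or no composition scaling in place of TMM, no low-count filter or a stricter one (5 CPM in 3 libraries), DESeq2 1.42.0, limma-voom with sample quality weights, a fit of only the 6 libraries compared, the replicate number as a block, a threshold of 2-fold, receptor segment and mitochondrial genes left out, and each library left out in turn. Chosen after seeing the data were T cell core scaling, with library factors from the summed counts of 10 genes (Cd3d, Cd3e, Cd3g, Cd247, Trac, Trbc1, Trbc2, Lck, Cd8a and Cd8b1), and bounds that leave out genes for which RNA of dendritic or melanoma cells could reach a share of 0.5 of the difference. T cell core scaling takes these transcripts as equal in each T cell, which was not tested.

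Counting depth was 9714020 to 15030442 reads in genes. Correlations of log CPM between libraries of a group were 0.900 to 0.906 in SiaHi_PD1neg and 0.939 to 0.985 in the PD-1-positive groups. The biological coefficient of variation was 0.313 over all libraries, and 0.490, 0.287 and 0.132 in SiaHi_PD1neg, SiaHi_PD1pos and SiaLo_PD1pos. Replicates spread more than sampling noise allows, with chi-square values of 7.04 to 57.9 per degree of freedom.

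The procedure was tested on simulated data with 200 genes changed, in a single draw per comparison. Counts were drawn at the real library sizes, with each gene's mean over all libraries and its dispersion from the shared fit. Every group thus had the same spread, unlike the real groups, so recovery and false calls may differ there. For SiaLo_PD1pos against SiaHi_PD1pos (14730 genes in the step), edgeR recovered 7.46% of genes changed 1.5-fold, 43.3% at 2-fold and 74.2% at 4-fold, with 3 of 86 calls false (3.49%). For the other comparisons it recovered 46.3% and 53.7% at 2-fold, with 6 of 89 and 7 of 93 calls false. DESeq2 made 23 false calls of 123 (18.7%) in the first comparison and limma-voom 2 of 81. Each planted list was found and 0 unchanged lists were called. Genes were drawn independently, so this does not test the lists where genes are correlated.

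Mean counts, tests and figures were computed only from the table of counts. Raw reads, splicing, variants and the single-cell data that the series description mentions were not analysed here.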

Results

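Polyadenylated RNA was sequenced from CD8-positive T cells sorted out of mouse melanomas. The sample labels name the tumour as B16-OVA, a B16 melanoma line that expresses chicken ovalbumin, while the series description names B16F10, a subline of the same melanoma. All mice were wild type and untreated. The cells were separated by flow cytometry on surface α2,6-linked sialoglycans and on PD-1, the inhibitory receptor encoded by Pdcd1. This gave 3 groups with 3 libraries each: sialoglycan high and PD-1 negative (SiaHi_PD1neg), sialoglycan high and PD-1 positive (SiaHi_PD1pos), and sialoglycan low and PD-1 positive (SiaLo_PD1pos). The table listed 56860 genes. Total counts were 13841619, 13475168 and 9714020 in SiaHi_PD1neg replicates 1, 2 and 3, 13165721, 13702189 and 12337273 in SiaHi_PD1pos, and 15030442, 14186412 and 11396686 in SiaLo_PD1pos. The first principal component held 54.6% of the variance and set the 3 SiaHi_PD1neg libraries apart from the 6 PD-1-positive libraries. Nothing in the labels says that replicates came from separate animals or tumours, so the p-values measure only the spread between these libraries, which may be technical.

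Transcripts of the sorted proteins were measured first. Levels are given as CPM, counts scaled to a common library total with TMM factors, as mean and SD over 3 libraries. Pdcd1, which the file places on chromosome 1 from 93966027 to 93980278 on the minus strand, was at 54.9 CPM (SD 20.9) in SiaHi_PD1neg, 898.5 CPM (SD 38) in SiaHi_PD1pos and 1122 CPM (SD 35.8) in SiaLo_PD1pos. St6gal1, the enzyme that adds α2,6-linked sialic acid to N-glycans, lies on chromosome 16 from 23043490 to 23179100 on the plus strand of the file's coordinates. It was at 98.6 CPM (SD 10.1), 63.8 CPM (SD 8.20) and 12.3 CPM (SD 5.20) in the same order. Cd8a, on chromosome 6 from 71350411 to 71356157 on the plus strand, was at 444.4 CPM (SD 41.3), 1419 CPM (SD 69.3) and 1674 CPM (SD 112). Cd8b1, the other chain of the CD8 co-receptor, was at 254.8 CPM (SD 17.1), 764.1 CPM (SD 103) and 801.3 CPM (SD 57.6). Cd3e, a signalling chain of the T cell receptor complex, was at 61.2 CPM (SD 5.64), 359.7 CPM (SD 16.1) and 417.1 CPM (SD 19.3). Cd4, the co-receptor of helper and regulatory T cells that dendritic cells also transcribe, was at 320.3 CPM (SD 80.5), 32.9 CPM (SD 7.18) and 4.18 CPM (SD 1.86). The file does not name its genome build, and its coordinates differ from GRCm38.

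**Figure D1:**
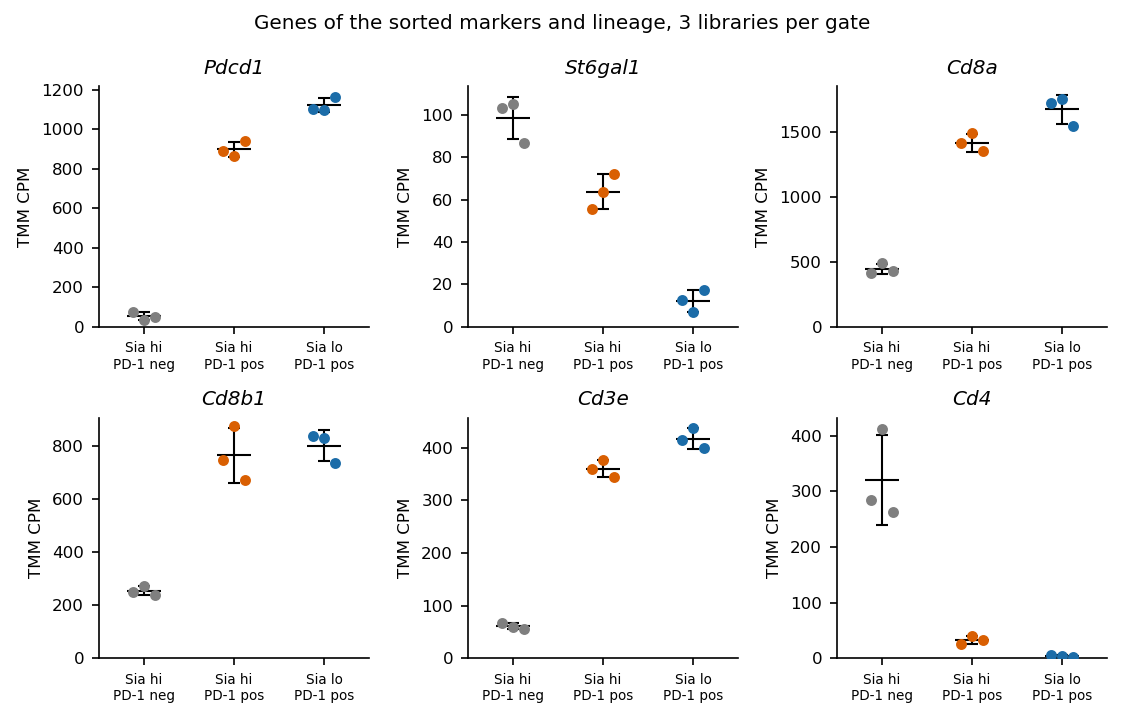
Level of 6 transcripts in each library, in TMM-scaled CPM on a linear axis from 0, with 1 panel per gene; points are libraries (grey SiaHi_PD1neg, orange SiaHi_PD1pos, blue SiaLo_PD1pos) and bars are the mean and SD of 3. Pdcd1 was at 54.9, 898.5 and 1122 CPM in the 3 groups and St6gal1 at 98.6, 63.8 and 12.3 CPM.

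The comparison of SiaLo_PD1pos with SiaHi_PD1pos asked whether PD-1-positive intratumoral CD8 T cells with little or much α2,6-sialylation differ in phenotype, a link that the submitters describe from single-cell data. The sialoglycan-low cells had less RNA of genes kept by naive, memory and stem-like T cells. Tcf7, the transcription factor TCF-1 of stem-like T cells, fell 3.38-fold from 194.4 CPM (SD 24.0, n = 3) to 57.5 CPM (SD 11.1, n = 3), a log2 fold change of -1.76 (SE 0.16, adjusted p = 5.67e-05). Dapl1 fell 8.70-fold from 45.0 CPM (SD 3.87) to 5.18 CPM (SD 0.485). Of 25 cytotoxicity genes 2 passed as higher, and the list's own test was lost at an adjusted p = 0.497 with an estimated correlation. Prf1, the pore-forming protein perforin, rose 1.84-fold from 283.8 CPM (SD 21.0) to 522.3 CPM (SD 58.8), with an adjusted p of 0.00784. Cx3cr1, the fractalkine receptor of effector T cells, rose 2.21-fold from 49.2 CPM (SD 2.81) to 108.8 CPM (SD 4.4), with an adjusted p of 0.00478. St6gal1 itself fell 5.19-fold (log2 -2.38, SE 0.25, adjusted p = 2.54e-04), while Pdcd1 (log2 0.32, adjusted p = 0.819), Cd8a (0.24, 0.669), Cd8b1 (0.07, 1) and Cd3e (0.21, 0.698) did not pass the test.

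Gene lists fixed before the data were examined were then counted. Of the 24 naive, memory and stem-like genes, 13 fell, 0 rose and 11 did not pass (17 lower when adjusted over the list alone; camera adjusted p = 1.28e-45, held at 0.00981 with an estimated correlation). Besides Tcf7 and Dapl1, they included Slamf6 (log2 -1.78), a surface marker of progenitor exhausted cells, the lymphoid homing receptor Ccr7 (-1.60) and Il7r (-1.78), the interleukin-7 receptor. The last 3 were chosen after their values were seen, as were Itga1, Tyr, Klri2 and Klra7 in the lists that follow. Of 14 costimulatory receptors and ligands, 3 fell, 0 rose and 11 did not pass (7 lower over the list alone; adjusted p = 2.95e-06, held at 0.0158 with an estimated correlation). These were Tnfsf8, the CD30 ligand, which fell 3.80-fold, Tnfrsf4, the receptor OX40, at log2 -1.10, and Il2ra at -0.78. Il2ra encodes a chain of the interleukin-2 receptor, a cytokine receptor, and is also in the CD4 and regulatory T cell list. The call of Il2ra ended without SiaHi_PD1pos replicate 1 or 3 or SiaLo_PD1pos replicate 1 or 3, with an adjusted p of up to 0.101. MHC class II and dendritic cell transcripts and Cd4 were lower in the same libraries, as given with the marker lists.

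Of 24 inhibitory receptor and exhaustion genes, 3 rose, 0 fell and 21 did not pass (10 higher and 2 lower over the list alone; camera adjusted p = 6.98e-04, adjusted p = 0.0812 with an estimated correlation). Havcr2, the receptor TIM-3, went from 174.2 CPM (SD 5.21) to 303.9 CPM (SD 59.3), Cd244a, the receptor 2B4, had a log2 fold change of 0.76 and Adgrg1 of 0.92. None of these 3 calls was kept under T cell core scaling, where the fold changes stayed positive at 0.68, 0.65 and 0.78. Without composition scaling the calls of Havcr2 (adjusted p = 0.0627) and Adgrg1 (adjusted p = 0.054) were lost too. That of Havcr2 was also lost with DESeq2's size factors (adjusted p = 0.0509). Without single libraries the adjusted p of Havcr2 reached 0.220 (call lost without SiaHi_PD1neg replicate 1, any SiaHi_PD1pos replicate, or SiaLo_PD1pos replicate 1 or 2), that of Adgrg1 0.164 (any of the 6 PD-1-positive libraries) and that of Cd244a 0.107 (SiaHi_PD1pos replicate 1 or any SiaLo_PD1pos replicate). Of 25 cytotoxicity and effector cytokine genes, Prf1 and Cx3cr1 rose, 0 fell and 23 did not pass (7 higher over the list alone). That list's camera adjusted p was 0.00102, lost at an adjusted p = 0.497 with an estimated correlation. Without single libraries it was at 9.61e-11 to 0.0527, the call ending without SiaHi_PD1pos replicate 1. Among 10 chemokines made by T cells, Ccl5 rose 1.92-fold to 1295 CPM (SD 97.9), Xcl1, which attracts XCR1-positive dendritic cells, fell 2.32-fold from 639.8 CPM (SD 260.6) to 275.7 CPM (SD 32.2), and 8 did not pass (list adjusted p = 0.373; 2 higher and 4 lower over the list alone). The chemokine list was at 0.0457 to 0.795 without single libraries and passed without SiaHi_PD1pos replicate 1 or 3. Its direction was not the same in all of these fits. The Xcl1 call ended without SiaLo_PD1pos replicate 2 or 3, where its adjusted p reached 0.0992.

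Tissue residency and retention genes went both ways. Itgae, the integrin CD103 that binds E-cadherin, fell 9.72-fold from 23.3 CPM (SD 1.28) to 2.41 CPM (SD 0.845), and Cxcr3, the receptor of interferon-induced chemokines, was at log2 -0.87. Some dendritic cells also carry CD103: 10 of 17 dendritic cell genes were lower in the same libraries, Itgae was at 129.5 CPM in SiaHi_PD1neg, and dendritic cell RNA at that group's level could reach a share of 0.674 of its difference. In all 2 genes fell and 2 rose, among them Itga1 (0.70), the collagen-binding integrin CD49a, and 9 of 13 genes did not pass (3 higher and 4 lower over the list alone; camera adjusted p = 0.0641 towards lower, against a median of 0.08). Without single libraries the list was at 0.0383 to 0.181 and passed in 3 of 9 fits, without SiaHi_PD1neg replicate 2, SiaHi_PD1pos replicate 1 or SiaLo_PD1pos replicate 2. In T cell core scaling the list's median was -0.05, and the call of Itga1 was lost. Calls of Cxcr3 and Itga1 were lost without single libraries, with an adjusted p of up to 0.106 for Cxcr3 (SiaHi_PD1pos replicate 1, SiaLo_PD1pos replicate 1 or 3) and 0.236 for Itga1 (SiaHi_PD1neg replicate 3, any PD-1-positive library).

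Among 5 tested α2,6 sialyltransferases, St6gal1 was the 1 that fell, with 4 not past the threshold (1 lower over the list alone; camera adjusted p = 0.00176, adjusted p = 0.0753 with an estimated correlation). Of 9 other sialyltransferases, St8sia1, which makes the ganglioside GD3, fell from 4.67 to 0.426 CPM (log2 -3.43, adjusted p = 0.00106), and 8 did not pass (1 lower over the list alone; list adjusted p = 0.00265, adjusted p = 0.0753 with an estimated correlation). None of 11 genes of sialic acid synthesis, transport and removal passed in edgeR (1 lower over the list alone and 1 at an unadjusted p under 0.05, by DESeq2 and by limma-voom; list adjusted p = 0.676, towards lower against a median of 0.02). None of 17 N-glycan branching genes passed (0 at an unadjusted p under 0.05 and in DESeq2, 1 lower in limma-voom; list adjusted p = 0.518). None of 12 O-glycan genes passed in edgeR (1 higher and 1 lower unadjusted and in limma-voom, 1 lower over the list alone and in DESeq2; list adjusted p = 0.531).

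Of 29 immediate early and heat shock genes, Egr2, Egr3 and Atf3 fell, 0 rose and 26 did not pass (1 higher and 5 lower over the list alone; camera adjusted p = 0.00169, adjusted p = 0.576 with an estimated correlation). The first 2 of these transcription factors are induced by T cell receptor signals. Each of the 3 calls ended without any 1 of the SiaLo_PD1pos libraries. Calls also ended for Egr2 without SiaHi_PD1pos replicate 1 or 2, for Egr3 without SiaHi_PD1pos replicate 1 or 3, and for Atf3 without SiaHi_PD1pos replicate 3 or any SiaHi_PD1neg library, at adjusted p values of up to 0.167, 0.109 and 0.167. The call of Atf3 also ended in a fit of only the 6 libraries, at 0.0834. The list's own adjusted p was 3.57e-05 to 0.198 without single libraries, its call ending without SiaHi_PD1pos replicate 2. The 29 tested type I interferon genes were lower as a list (adjusted p = 0.00169, adjusted p = 0.352 with an estimated correlation; median log2 -0.17) with 0 members past the threshold in edgeR, 5 lower at an unadjusted p under 0.05 and 1 lower in DESeq2 and in limma-voom. The 12 mitochondrially encoded mRNAs were higher as a list (adjusted p = 1.37e-04, adjusted p = 0.491 with an estimated correlation; 1.32e-10 to 0.0765 without single libraries, the call ending without SiaHi_PD1pos replicate 3; median 0.51). Of their members 0 passed the threshold in edgeR, 3 at an unadjusted p under 0.05, 1 in DESeq2 and 7 in limma-voom.

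Cell division and metabolism lists did not pass between the PD-1-positive groups. The camera adjusted p was 0.409 for 30 S phase genes, 0.0589 for 30 G2 and mitosis genes, 0.518 for 24 T cell receptor signalling genes, 0.518 for 20 glycolysis genes, 0.326 for 45 oxidative phosphorylation genes and 0.339 for 21 cholesterol synthesis genes, and 0 members passed in edgeR. At an unadjusted p under 0.05 these lists had 0 members apart from 1 higher and 1 lower in glycolysis and 1 lower in oxidative phosphorylation. DESeq2 called 0 of them, and limma-voom called 3 lower in S phase, 1 higher in G2 and mitosis, 2 higher and 1 lower in receptor signalling, and 1 higher and 1 lower in glycolysis. Without single libraries the G2 and mitosis list was at 0.00264 to 0.524 and passed in 7 of 9 fits, failing without SiaHi_PD1pos replicate 3 (0.250) and SiaLo_PD1pos replicate 2 (0.524). Oxidative phosphorylation (1.47e-04 to 0.595) passed towards higher without SiaHi_PD1pos replicate 2 and towards lower without SiaHi_PD1pos replicate 3. S phase (0.0459 to 0.995) passed without SiaHi_PD1pos replicate 3 and glycolysis (0.0487 to 0.972) without SiaHi_PD1pos replicate 2. The direction of both lists was not the same in all of these fits.

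Markers of other cell types differed between the same libraries. Melanoma genes were higher in SiaLo_PD1pos, with a summed level of 2447 CPM (SD 889) against 944.7 CPM (SD 67.5), and of 14 tested, Tyrp1, Dct and Tyr rose and 11 did not pass (14 higher over the list alone; camera adjusted p = 1.15e-23, adjusted p = 0.0531 with an estimated correlation). Tyrp1, a melanin enzyme, was at 838.4 CPM (SD 296) against 312.8 CPM (SD 15.9), and its call ended without SiaHi_PD1pos replicate 1 or 2, at up to 0.0971, as did that of Dct, at up to 0.105. Under T cell core scaling 0 melanoma genes passed in edgeR, with the list median still positive at 1.21. Dendritic cell and MHC class II genes were lower, from 4039 CPM (SD 1300) to 2159 CPM (SD 201), with 10 of 17 lower, 0 higher and 7 not past (13 lower over the list alone; adjusted p = 2.98e-39, held at 0.00278). Cd74, the class II invariant chain, was at 1377 CPM (SD 481) against 684.1 CPM (SD 91.8); its call ended without SiaHi_PD1neg replicate 1 or 3 or any SiaLo_PD1pos replicate, at up to 0.144, and in a fit of only the 6 libraries, at 0.0611. B and plasma cell genes were lower in 4 of 11, with Ighm, the immunoglobulin heavy chain, at 103.6 against 255.3 CPM (8 lower over the list alone; adjusted p = 1.39e-18, held at 8.33e-04). CD4 and regulatory T cell genes were lower in 3 of 12 (5 over the list alone; adjusted p = 2.64e-11, held at 0.00186), and these were Cd4, Il2ra and Foxp3, the regulatory T cell factor, which fell 10.1-fold from 20.1 CPM (SD 3.05) to 2.00 CPM (SD 0.556). The call of Il2ra rests on single libraries, with an adjusted p of up to 0.101 without SiaHi_PD1pos replicate 1 or 3 or SiaLo_PD1pos replicate 1 or 3.

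The remaining marker lists had fewer calls. Of 20 macrophage and monocyte genes 0 passed in edgeR, with 6 lower over the list alone and at an unadjusted p under 0.05, 3 lower in DESeq2 and 2 in limma-voom (list adjusted p = 3.84e-06, adjusted p = 0.281 with an estimated correlation). Its most abundant member, Apoe, was at 410.7 CPM (SD 75.7) against 485.2 CPM (SD 131). Natural killer cell genes had Klre1 and Klri2 higher and Klra7 lower of 11 (list adjusted p = 0.355). Klre1, at 183.6 against 86.4 CPM, lost its call without SiaHi_PD1pos replicate 1 or 3 or SiaLo_PD1pos replicate 2, at up to 0.0699, Klra7 without SiaHi_PD1pos replicate 1 or SiaLo_PD1pos replicate 1 or 2, at up to 0.0779, and Klri2 without SiaHi_PD1pos replicate 1 or 3 or any SiaLo_PD1pos replicate, at up to 0.167. The 4 tested gamma-delta genes were lower as a list (adjusted p = 0.0115, adjusted p = 0.167 with an estimated correlation) with 0 members called in edgeR and DESeq2, 1 lower in limma-voom and 1 lower at an unadjusted p under 0.05. Lists of neutrophil (0.105), endothelial (0.355) and fibroblast genes (0.903) did not pass, with 0 members called in edgeR or DESeq2. At an unadjusted p under 0.05, 2 neutrophil genes were lower, and limma-voom called 1 higher and 2 lower neutrophil genes, 1 lower endothelial gene and 1 higher fibroblast gene. The erythroid genes, with 1 of 9 tested, were too few for a list test.

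**Figure D2:**
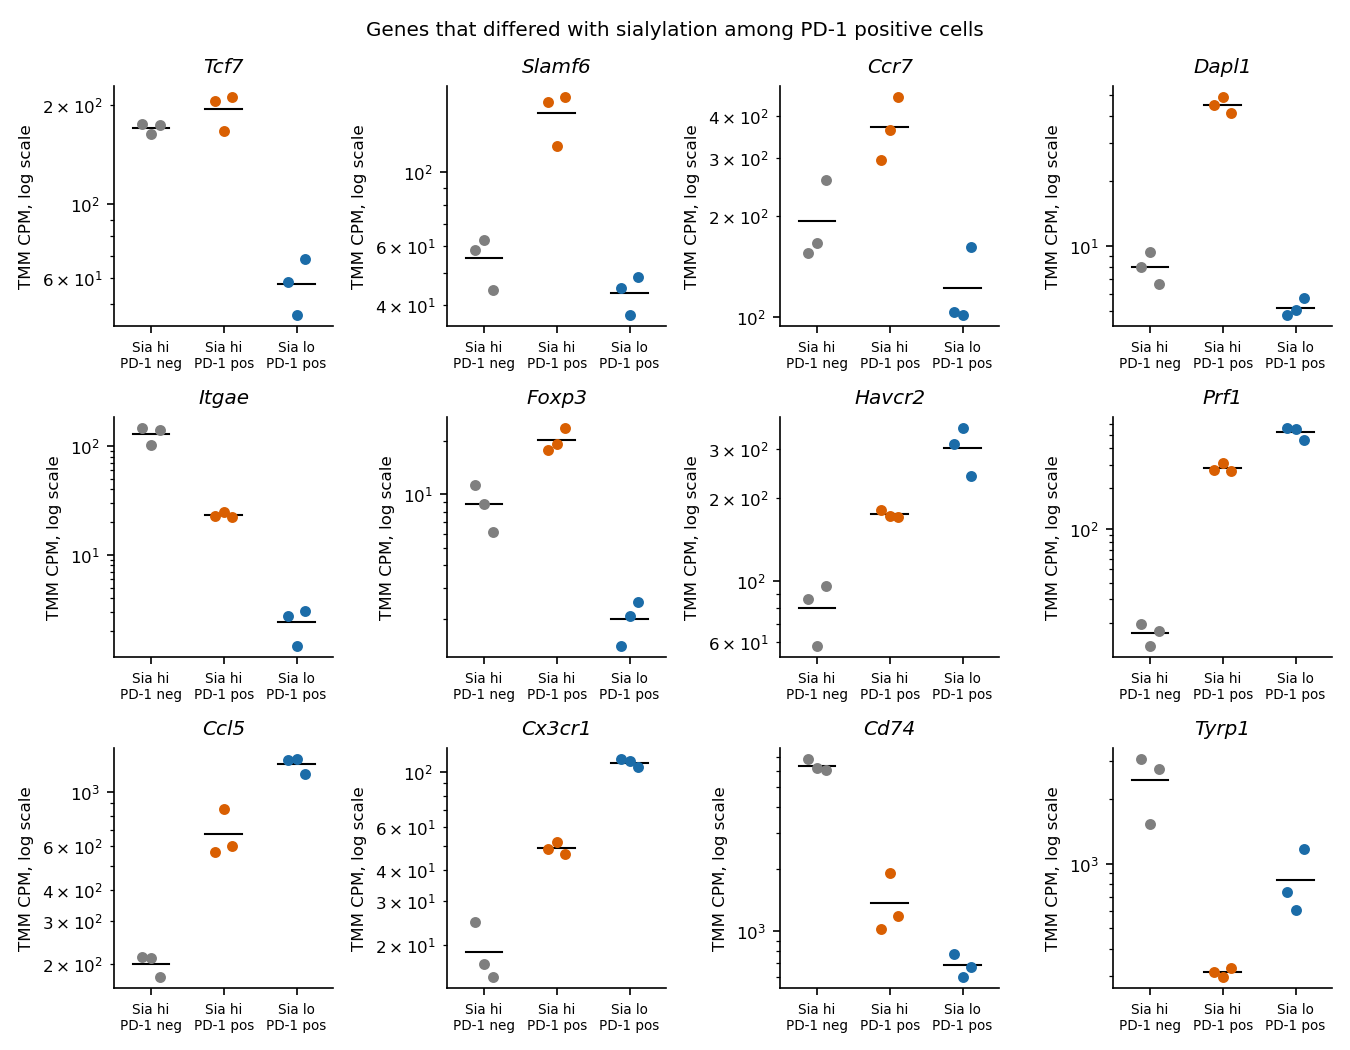
Level of 12 transcripts in each library, in TMM-scaled CPM on a log axis, with 1 panel per gene; points are libraries by group and the bar is the mean of 3. Tcf7, Slamf6, Ccr7, Dapl1, Itgae, Foxp3 and Cd74 were lower and Havcr2, Prf1, Ccl5, Cx3cr1 and Tyrp1 higher in SiaLo_PD1pos than in SiaHi_PD1pos, in all 3 libraries against all 3.

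The genes with the largest differences by the fixed rule were mixed in kind. The 8 lowest were Foxp3, Itgae, Ccl22, Lif, Jchain, Dapl1, Il12b and Nsg2, with log2 fold changes between -3.33 and -2.98; Ccl22, a chemokine of dendritic cells, fell from 17.4 to 1.82 CPM and Il12b, a subunit of interleukin-12, from 14.9 to 1.74 CPM. The 8 highest included Clgn, Nrcam, Tspan10, Gsta4, Dct, Syt4 and Tyrp1, between 1.66 and 1.42, and Dct, another melanin enzyme, rose from 226.3 to 624.2 CPM. Of these 16, calls ended without single libraries for Jchain, Clgn, Nrcam, Tspan10, Gsta4, Dct, Syt4 and Tyrp1, at adjusted p values of up to 0.120, 0.161, 0.0900, 0.158, 0.157, 0.105, 0.0990 and 0.0971. The libraries were SiaHi_PD1pos replicate 2 or 3 or SiaLo_PD1pos replicate 1 or 2 for Jchain and all 6 PD-1-positive libraries for Clgn. They were SiaHi_PD1pos replicate 1 or 2 for Nrcam, Dct and Tyrp1, with SiaLo_PD1pos replicate 3 as well for Nrcam. For the others they were 5 of the 6 PD-1-positive libraries: all but SiaLo_PD1pos replicate 2 for Tspan10 and Syt4 and all but SiaHi_PD1pos replicate 2 for Gsta4. SiaHi_PD1neg replicate 3 ended the calls of Gsta4 and Tspan10 too, and SiaHi_PD1neg replicate 1 that of Tspan10.

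Of 15292 tested genes, 41 were higher and 173 lower in SiaLo_PD1pos (edgeR quasi-likelihood test, adjusted p under 0.05), 23 and 145 of them by at least 2-fold. The libraries of both groups did not overlap for 2962 genes (19.4%, where chance gives 10%). The number of higher genes ranged from 14 (without SiaHi_PD1pos replicate 1 or SiaLo_PD1pos replicate 3) to 66 (without SiaHi_PD1neg replicate 2), at 17 without SiaHi_PD1pos replicate 3 or SiaLo_PD1pos replicate 1, and that of lower genes was 97, 81 and 91 without SiaLo_PD1pos replicate 1, 2 and 3. DESeq2 gave 130 higher and 340 lower, limma-voom with sample weights 541 and 732, and a fit of only the 6 libraries 71 higher.

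The comparison of SiaHi_PD1pos with SiaHi_PD1neg asked how PD-1-positive and PD-1-negative cells differ at a high sialoglycan level. PD-1-positive libraries had more RNA of activated and dividing T cells and less RNA of several non-T cell types. Pdcd1 rose 16.3-fold (log2 4.03, SE 0.23, adjusted p = 5.38e-08). Prf1 rose 16.8-fold from 16.9 CPM (SD 3.15, n = 3) to 283.8 CPM (SD 21.0, n = 3), Tnfrsf9, the costimulatory receptor 4-1BB, 10.8-fold from 40.0 to 431.0 CPM, and Ctla4, an inhibitory receptor, 5.71-fold from 148.4 CPM (SD 6.89) to 846.7 CPM (SD 24.2). Transcripts that define CD8 T cells were higher too, Cd8a by 3.19-fold and Cd3e by 5.87-fold. The 10 T cell core genes (Cd3d, Cd3e, Cd3g, Cd247, Trac, Trbc1, Trbc2, Lck, Cd8a and Cd8b1), chosen after their values were seen, had a median of 3.91-fold. Scaling on their summed counts therefore shifted the median log2 fold change of all genes to -1.87 (-1.99 between SiaLo_PD1pos and SiaHi_PD1neg).

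Proliferation genes rose on the TMM scale. Of 30 S phase genes 30 rose, among them the replication helicase gene Mcm6 from 130.2 to 475.2 CPM and the nucleotide enzyme gene Dut. Of 30 G2 and mitosis genes 29 rose and 1 did not pass, with the topoisomerase Top2a going from 165.7 to 604.5 CPM and Nusap1 at 2.10. Both lists passed (30 and 29 higher over each list alone; camera adjusted p = 6.82e-29 and 7.17e-23, held at 0.0195 and 0.0179 with an estimated correlation). Relative to the T cell core genes the medians of both lists turned from 1.72 to -0.17 and -0.18, with 1 S phase gene higher and 9 and 8 genes lower. Inhibitory receptor and exhaustion genes rose in 18 of 24, fell in 2 and did not pass in 4 (the same over the list alone; adjusted p = 1.59e-15, held at 0.00424), led by Rgs16 (log2 3.89), Ctla4 and the receptor Tigit (2.71), with a median of 1.41 that turned to -0.46 under that scaling (6 higher and 10 lower). Of 25 cytotoxicity genes 17 rose and 3 fell (the same over the list alone; adjusted p = 1.19e-16, adjusted p = 0.0608 with an estimated correlation), with the death ligand Fasl at 3.17 and the transcription factor Tbx21 at 2.48. Their median stayed positive, 2.15 on the TMM scale and 0.26 per T cell core transcript, where 11 were higher and 12 lower.

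Signalling lists turned in the same way. Costimulatory genes rose in 13 of 14 and fell in 1 (the same over the list alone; adjusted p = 1.03e-16, held at 0.00156; median 1.69, and -0.23 under T cell core scaling). T cell receptor signalling genes rose in 19 of 24 and fell in 1 (the same over the list alone; adjusted p = 1.88e-19, held at 0.00156; 1.52, and -0.37), with the kinase Zap70 at 2.64. Its members Cd3d, Cd3e, Cd3g, Cd247, Lck, Cd8a and Cd8b1 also set that scaling, so the turn of this list was partly fixed beforehand. Chemokine genes rose in 6 of 10 and fell in 3 (the same over the list alone; adjusted p = 0.0130, adjusted p = 0.436 with an estimated correlation; 1.34, and -0.59), with Ccl1 at 5.67, Xcl1 at 3.30 and Ccl5 at 1.75 but -0.17 under T cell core scaling. Oxidative phosphorylation genes rose in 12 of 45 (7 over the list alone; adjusted p = 0.0294, adjusted p = 0.688 with an estimated correlation; 0.30, and -1.64); without single libraries it was at 3.85e-04 to 0.416, and the call ended without SiaHi_PD1neg replicate 3 or SiaHi_PD1pos replicate 2.

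Other lists were lower on the TMM scale. Type I interferon genes fell in 19 of 29 and rose in 2 (2 higher and 21 lower over the list alone; adjusted p = 8.27e-10, held at 0.0483; median -1.02), with Ifi44 at log2 -2.58 and the antiviral gene Oasl1 at -2.31. Mitochondrially encoded mRNAs fell in 11 of 12 (11 over the list alone; adjusted p = 6.28e-06, adjusted p = 0.342 with an estimated correlation), with mt-Nd5 at -1.58; they took 8.12% (SD 1.91) of counts in SiaHi_PD1neg, 2.87% (SD 0.656) in SiaHi_PD1pos and 4.23% (SD 0.791) in SiaLo_PD1pos. Sialyltransferases other than the α2,6 type fell in 7 of 9 (7 over the list alone; adjusted p = 0.00300, held at 0.0483), with St3gal5 at -2.55 and St8sia4, which builds polysialic acid, from 373.8 to 110.0 CPM. Cholesterol synthesis genes fell in 8 of 21 and rose in 1 (10 and 1 over the list alone; adjusted p = 0.00588, adjusted p = 0.429 with an estimated correlation), with Fdps at -1.36. Immediate early genes fell in 12 of 29 and rose in 6 (13 and 7 over the list alone; adjusted p = 0.0155, adjusted p = 0.543 with an estimated correlation; 9.71e-04 to 0.0629 without single libraries, the call ending without SiaHi_PD1pos replicate 1), with the AP-1 genes Fos, from 1320 to 347.9 CPM, and Jun at -1.79.

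Other lists did not pass on the TMM scale. Naive, memory and stem-like genes rose in 9 and fell in 9 of 24 (the same over the list alone; adjusted p = 0.472; median -0.01, and -1.90 under T cell core scaling). Cd27, a memory costimulatory receptor, was at 1.90, or -0.01 under that scaling, and Dapl1 at 2.49. Residency genes rose in 5 and fell in 4 of 13 (the same over the list alone; adjusted p = 0.210), with the chemokine receptors Ccr8 at 3.69 and Cxcr6 at 2.91. Glycolysis genes rose in 8 of 20 and fell in 1 (the same over the list alone; 0.113), with the lactate transporter Slc16a1 at 1.62, or -0.28 under T cell core scaling. N-glycan branching genes rose in 2 and fell in 8 of 17 (3 and 8 over the list alone; 0.210), and O-glycan genes rose in 6 and fell in 2 of 12 (the same over the list alone; 0.210). Sialic acid synthesis genes rose in 1 and fell in 2 of 11 (the same over the list alone; 0.486). Without single libraries glycolysis was at 0.0132 to 0.218, passing without SiaHi_PD1neg replicate 1 or SiaHi_PD1pos replicate 3, and O-glycan synthesis at 0.0426 to 0.269, passing without SiaHi_PD1neg replicate 3. Of 5 tested α2,6 sialyltransferases, St6galnac3 (2.31) and St6galnac4 (0.60) rose and St6gal1 fell (the same over the list alone; 0.644, towards higher against a median of -0.04). The fall of St6gal1 was small, log2 -0.63 (SE 0.24, adjusted p = 0.0483), and its call ended without any 1 of the 6 libraries compared or SiaLo_PD1pos replicate 1 (0.0172 to 0.175 over the 9 libraries left out), without composition scaling, at 0.0508, and without receptor segment and mitochondrial genes, at 0.0527.

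Other cell types were marked more strongly in SiaHi_PD1neg. Melanoma genes were lower in SiaHi_PD1pos in 14 of 14 (summed 944.7 CPM against 6771 CPM, SD 2414; adjusted p = 4.4e-12, adjusted p = 0.221 with an estimated correlation), with Tyrp1 at 312.8 against 2441 CPM. Dendritic cell and MHC class II genes were lower in 15 of 17 (4039 against 20370 CPM, SD 1228; adjusted p = 2.00e-24, held at 0.0119), with Cd74 at 1377 against 6368 CPM (SD 432). Macrophage genes were lower in 18 of 20 (adjusted p = 1.14e-06, adjusted p = 0.249 with an estimated correlation), and endothelial genes in 10 of 12 (7.47e-06; adjusted p = 0.221 with an estimated correlation). The same held for fibroblast genes in 13 of 14 (7.47e-06; adjusted p = 0.249 with an estimated correlation) and B and plasma cell genes in 7 of 11 (1.55e-04, held at 0.0318). Adjusted over the list alone the lower counts were 14, 15, 19, 10, 13 and 7 in the order given. CD4 and regulatory T cell genes rose in 5 and fell in 2 of 12 (0.205), with Cd4 at log2 -3.28 and Il2ra at 2.56. Natural killer genes rose in 2 and fell in 4 of 11 (0.472), neutrophil genes rose in 2 of 4 (0.252), and 1 of 4 gamma-delta genes fell (0.572), a call not kept over the list alone.

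**Figure D3:**
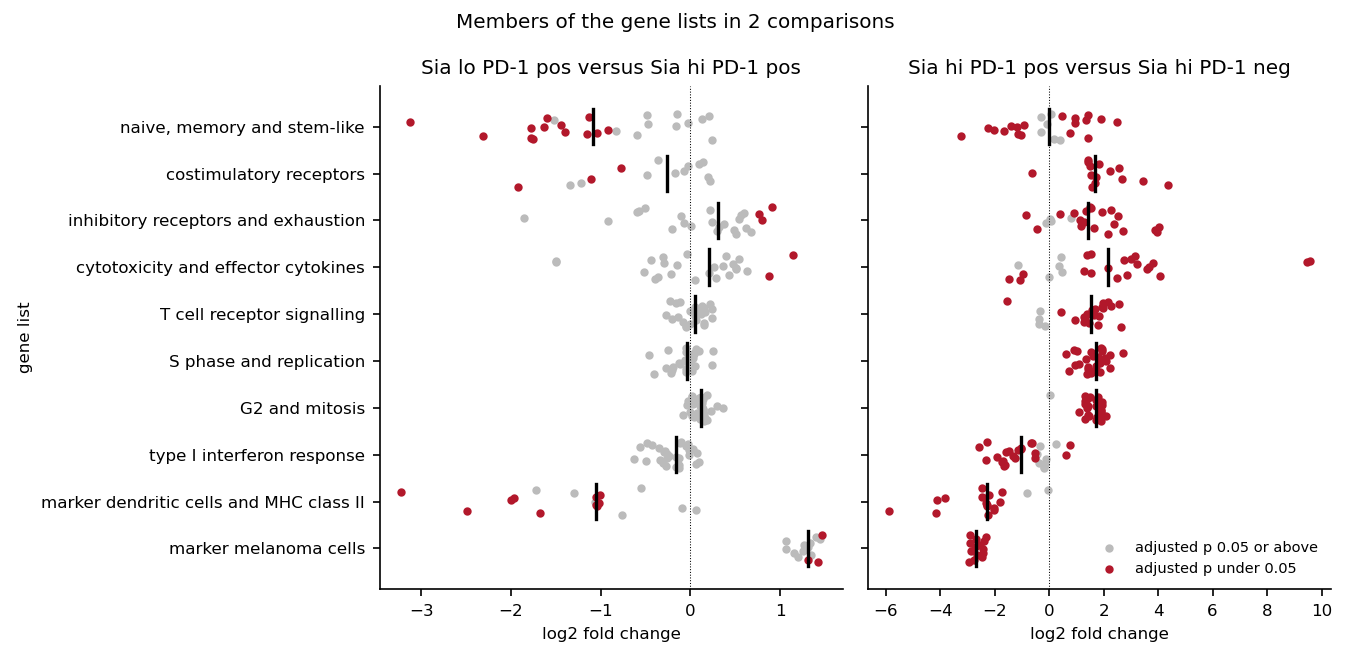
Log2 fold change of each tested member of 10 gene lists, SiaLo_PD1pos against SiaHi_PD1pos on the left and SiaHi_PD1pos against SiaHi_PD1neg on the right; red points had an adjusted p under 0.05, grey points did not, and black bars are list medians. On the right the medians of the costimulatory, exhaustion, receptor signalling, S phase and mitosis lists, 1.41 to 1.72 on the TMM scale plotted, turn to between -0.46 and -0.17 under T cell core scaling. The receptor signalling list shares members with the genes that set that scaling.

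Among the 8 highest genes of the fixed rule were Rgs8 (log2 5.95), the lectin-like receptor Klrh1 (5.76) and Ccl1 (5.67), and among the 8 lowest were the kallikrein Klk1 (-6.03), from 421.7 to 6.44 CPM, Dntt (-6.01), the terminal transferase, and Cd300c (-5.95). The table called 3218 genes higher and 2937 lower of 15292 (edgeR), 1439 and 2241 of them by at least 2-fold. Libraries did not overlap for 7269 genes (47.5%, where chance gives 10%), and under T cell core scaling 284 genes were higher and 12315 lower.

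The comparison of SiaLo_PD1pos with SiaHi_PD1neg joined both differences, and the labels state no separate question for it. Prf1 rose from 16.9 CPM (SD 3.15, n = 3) to 522.3 CPM (SD 58.8, n = 3), 31.0-fold, Fasl rose by log2 3.57 and the chemokine receptor Cxcr6 by 3.69. Il7r fell from 230.8 to 14.1 CPM and Klf2, a factor that maintains T cell quiescence, from 518.7 to 68.0 CPM. Itgae fell from 129.5 CPM (SD 23.7) to 2.41 CPM (SD 0.845). St6gal1 fell by 3.00 (adjusted p = 9.29e-07), St8sia1 by 5.64 and Cmah, which converts Neu5Ac to Neu5Gc sialic acid, from 171.1 to 23.8 CPM. Dendritic cell genes fell as well (list median log2 -3.33), and how far RNA of other cells shares in these falls was not tested. Tmprss6 and Clgn had no read in any SiaHi_PD1neg library. Tmprss6, a protease gene, at 26.1 CPM (SD 4.97) in SiaLo_PD1pos, was at least 325-fold higher, and Clgn, a chaperone gene, at 19.4 CPM (SD 0.752), at least 241-fold, against a floor of 3 counts over the group, which covers counting error only.

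Naive, memory and stem-like genes fell in 15 of 24 and rose in 4 (15 and 5 over the list alone; adjusted p = 3.93e-07, adjusted p = 0.110 with an estimated correlation; median -1.05, and -3.05 under T cell core scaling). Higher lists included exhaustion (19 of 24 higher, 2 lower; 1.17e-17, held at 0.00359), with Rgs16 at 4.38, Tigit at 3.00 and Ctla4 at 2.41, and cytotoxicity (18 of 25 higher, 3 lower; 2.28e-18, held at 0.0461), with Tbx21 at 2.76. They also included receptor signalling (19 of 24 higher, 1 lower; 2.28e-18, held at 0.00359) and costimulation (11 of 14 higher, 1 lower; 3.47e-10, held at 0.00359). Cell division lists were S phase (30 of 30 higher; 2.12e-24, held at 0.0266) and G2 and mitosis (29 of 30 higher; 2.39e-23, held at 0.0213). Over each list alone the counts were the same apart from 3 lower in receptor signalling. The medians of these lists were 1.51, 2.52, 1.59, 1.56, 1.71 and 1.82, and turned to -0.49, -0.42, -0.44, -0.30 and -0.19 under T cell core scaling for all but cytotoxicity, which was at 0.52. The receptor signalling list shares members with the genes that set this scaling, so its turn was partly fixed beforehand. Mcm6 was at 1.84 and Top2a at 2.03 on the TMM scale, or -0.17 and 0.02 under that scaling. Chemokines rose in 5 of 10 and fell in 2 (0.0311, adjusted p = 0.507 with an estimated correlation; 0.00735 to 0.0578 without single libraries, the call ending without SiaHi_PD1neg replicate 3), with Ccl5 at 2.69, and the list's median of 1.57 turned to -0.42.

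Lower lists were type I interferon (22 of 29 lower, 1 higher; 5.65e-12, held at 0.0287), with Ifi44 at -3.14, and other sialyltransferases (5 of 9 lower; 2.06e-04, held at 0.0265). They also included cholesterol synthesis (11 of 21 lower, 1 higher; 0.00220, adjusted p = 0.389 with an estimated correlation) and immediate early genes (13 of 29 lower, 4 higher; 7.77e-04, adjusted p = 0.449 with an estimated correlation), with Fos at -2.24. Mitochondrially encoded mRNAs were lower too (10 of 12 lower; 0.00257, adjusted p = 0.499 with an estimated correlation). Over each list alone the lower counts were 24, 5, 11, 15 and 11. Lists that did not pass were α2,6 sialyltransferases (0.515), sialic acid synthesis (0.444), N-glycan branching (0.348), O-glycan synthesis (0.156), residency (0.444), glycolysis (0.0839) and oxidative phosphorylation (0.103). Without single libraries glycolysis was at 0.0120 to 0.143, passing without SiaHi_PD1neg replicate 1, SiaHi_PD1pos replicate 2 or SiaLo_PD1pos replicate 1. Oxidative phosphorylation was at 0.0262 to 0.222, passing without the first 2 of these, and O-glycan synthesis at 0.0252 to 0.226, passing without SiaHi_PD1neg replicate 3. Dendritic cell genes were lower in 16 of 17 (adjusted p = 2.50e-37, held at 0.00367), with Cd74 at log2 -3.22, and melanoma genes in 13 of 14 (2.33e-04, adjusted p = 0.417 with an estimated correlation), with Tyrp1 at -1.54. Macrophage genes were lower in 19 of 20 (1.30e-09, adjusted p = 0.275 with an estimated correlation) and B and plasma cell genes in 9 of 11 (5.83e-09, held at 0.00367). Endothelial genes were lower in 11 of 12 (7.20e-05, adjusted p = 0.275 with an estimated correlation) and fibroblast genes in 13 of 14 (3.29e-05, adjusted p = 0.302 with an estimated correlation). Natural killer (0.345), CD4 (0.589), gamma-delta (0.261) and neutrophil lists (0.613) did not pass. In all, 3136 genes were higher and 2893 lower of 15292 (edgeR), 1468 and 2207 by at least 2-fold, and under T cell core scaling 281 were higher and 12531 lower; libraries did not overlap for 8319 genes (54.4%, where chance gives 10%).

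Some genes were called at both steps, from SiaHi_PD1neg to SiaHi_PD1pos and on to SiaLo_PD1pos. Of genes called in both adjacent comparisons, 124 were lower in both and 19 higher in both, where independent lists of the same sizes would share 33.2 and 8.63. Markers of dendritic cells fell at both steps, 15 and then 10 of 17, and Siglech, chosen after its values were seen, went from 888.5 to 15.02 to 2.63 CPM. Of genes called in opposite directions, 24 were higher in SiaHi_PD1pos than in both other groups, against 36.4 for independent lists, and 18 were lower, against 7.87. Because SiaHi_PD1pos libraries enter both comparisons with opposite signs, a negative correlation arises without any change. In 20 simulated data sets with no change the mean Pearson correlation across genes was -0.498, against -0.08 observed. The mean Spearman correlation was -0.448, against -0.100. The simulated sets lacked the changed genes that add variance to the observed values, so these correlations are not like for like. The covariance, which is not divided by that variance, was -0.159 on average when simulated and -0.0911 observed. Genes are not independent replicates, and 3 shared libraries cannot be split, so the share owed to them was not removed. Shared calls numbered 143 in the same direction, and 85 without SiaHi_PD1pos replicate 3 and 76, 62 and 68 without SiaLo_PD1pos replicate 1, 2 and 3. The Pearson correlation was -0.335 and -0.233 without SiaHi_PD1pos replicates 1 and 2, and 0.0902 with a stricter low-count filter.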

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

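Between SiaLo_PD1pos and SiaHi_PD1pos, where 41 genes were higher and 173 lower, the counts moved with the tool, the absence of a filter and the libraries used. DESeq2 gave 130 higher and 340 lower, limma-voom with sample weights 541 and 732, and no low-count filter 187 and 348. Fold thresholds of 2 left 23 higher, and the fit of only the 6 libraries gave 71. Higher genes made up 19.2% of calls, against 42.5% with limma-voom, 35.0% with no filter and 31.4% in the 6 libraries. Without single libraries their share was 9.27% (SiaHi_PD1pos replicate 1) to 28.45% (SiaHi_PD1neg replicate 2). The fit of all 9 libraries shares its spread with SiaHi_PD1neg. That group's biological coefficient of variation was 0.490, against 0.287 in SiaHi_PD1pos and 0.132 in SiaLo_PD1pos. The cause of these shifts was not tested. Under T cell core scaling 11 were higher, 5.09% of calls. Bounds chosen after seeing the data left 25 higher genes for which melanoma RNA could reach a share under 0.5 of the difference. They left 73 lower genes for which the same held of dendritic cell RNA. These counts follow from an assumed profile of that RNA, which was not measured.

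The larger comparisons depended on what was held constant. At least 2-fold, 1439 of 3218 higher genes remained between SiaHi_PD1pos and SiaHi_PD1neg and 1468 of 3136 between SiaLo_PD1pos and SiaHi_PD1neg. T cell core scaling, chosen after seeing the data, gave 284 higher and 12315 lower in the first (2.25% higher in place of 52.3%) and 281 and 12531 in the second (2.19% in place of 52.0%). This follows from its construction, as the genes held constant were higher in PD-1-positive cells. It turned log2 fold changes of the first to -0.17 for Ccl5, -0.00663 for Cd27, -0.22 for Cd8a, -0.32 for Cd8b1, -0.0278 for Mcm6, -0.28 for Slc16a1 and -0.0185 for Top2a, and of the second to -0.0934 for Cd8a, -0.35 for Cd8b1 and -0.17 for Mcm6. Among the 61, 47 and 29 genes run under every alternative in the 3 comparisons, no other alternative turned the sign of a called gene.

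With an estimated correlation, 2, 7 and 8 of the 20 lists passed in the 3 comparisons in the order of the report, where camera's preset gave 9, 13 and 13. Fry gave 5, 16 and 18. These tests ask different questions or widen the variance by construction.

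Leaving out single libraries gave 14 to 66 higher and 81 to 166 lower genes between SiaLo_PD1pos and SiaHi_PD1pos, 2639 to 3467 and 2246 to 2858 between SiaHi_PD1pos and SiaHi_PD1neg, and 2442 to 3662 and 2016 to 2956 between SiaLo_PD1pos and SiaHi_PD1neg. Lists past the threshold were 10 to 11, 12 to 14 and 13 to 15. Of the called genes among these, 27 of 57, 46 of 47 and 29 of 29 kept their call without each library. Shared calls in the same direction were 62 to 141 against 143. The correlation across genes of both adjacent comparisons, -0.08 with all libraries, was -0.335 to -0.0950 without single libraries and turned to 0.0902 with the stricter filter; the cause was not tested.

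Whether replicate numbers pair the libraries stays open. Deviations from group means correlated at -0.011 to 0.118 for libraries with the same number and at -0.145 to 0.0642 for others. Between SiaHi_PD1pos and SiaLo_PD1pos they correlated at 0.0617, 0.118 and 0.101 for the same number, and at -0.145 to 0.0540 for others. With the replicate block, 65 genes were higher and 199 lower between SiaLo_PD1pos and SiaHi_PD1pos, and the adjusted p was 0.0520 for Havcr2 and 0.0583 for Itga1. It changed no other call of a named gene or count of calls by over 1.5 times.

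Of the 61 genes run in the first comparison, 61 kept their side of the threshold in DESeq2, 58 in limma-voom, where Pdcd1 (0.0101), Cd8a (0.0195) and Cd3e (0.0464) passed as higher, 59 with DESeq2's size factors, 57 without composition scaling, 56 in the 6 libraries and 46 under T cell core scaling. In a simulation 43.3% of 2-fold changes were found in that comparison. It drew every group at the spread of the shared fit (biological coefficient of variation 0.313). SiaHi_PD1pos was at 0.287 and SiaLo_PD1pos at 0.132, so the share of such changes left uncalled in the real data is not known.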

Other observations

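Genes in this paragraph were chosen after their values were seen. Between SiaLo_PD1pos and SiaHi_PD1pos, more surface molecules and cytokines of T cells were lower. Btla, an inhibitory receptor of naive and progenitor cells, was at 27.4 CPM (SD 1.67) against 88.3 CPM (SD 10.5), log2 -1.69, and Cd200, the ligand of an inhibitory receptor of myeloid and T cells, at 45.0 CPM (SD 6.13) against 106.6 CPM (SD 6.90). Tnfsf11, the cytokine RANKL, was at 6.57 CPM (SD 1.40) against 42.4 CPM (SD 4.17), log2 -2.69, and Nt5e, the ectonucleotidase CD73, at 26.4 CPM (SD 3.09) against 64.8 CPM (SD 9.48). Il2, the T cell growth factor, was at 0.239 CPM (SD 0.184) against 7.60 CPM (SD 4.47), with an adjusted p of 0.0106 that was 0.0568 without SiaLo_PD1pos replicate 2. Crtam, an adhesion molecule of activated CD8 T cells, was at 94.8 CPM (SD 9.22) against 189.8 CPM (SD 41.2), adjusted p = 0.00926, or 0.0612 without SiaLo_PD1pos replicate 3.

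Families chosen after their values were seen differed too. Of 12 tested Klra receptors, the Ly49 family, 3 were lower between SiaLo_PD1pos and SiaHi_PD1pos (Klra1, Klra6 and Klra7; family median -0.79, and -0.89 under T cell core scaling), 6 were lower between SiaHi_PD1pos and SiaHi_PD1neg (-1.65, and -3.48) and 8 between SiaLo_PD1pos and SiaHi_PD1neg (-2.96, and -4.94). Klra7 was at 52.4, 7.71 and 2.81 CPM in SiaHi_PD1neg, SiaHi_PD1pos and SiaLo_PD1pos. Dendritic cell RNA with the profile of SiaHi_PD1neg, which was assumed, could reach a share of 0.908 of the Klra1 difference in the first comparison. For Klra6 and Klra7 that share was 1.08 and 1.16. Calls of the 3 genes in the first comparison ended without single libraries, at adjusted p values of up to 0.179 for Klra1 (all but SiaHi_PD1pos replicate 2 and SiaLo_PD1pos replicate 2), 0.161 for Klra6 (all but SiaHi_PD1pos replicate 2) and 0.0779 for Klra7 (SiaHi_PD1pos replicate 1, SiaLo_PD1pos replicate 1 or 2). A fit of only the 6 libraries also ended the calls of Klra1 (0.117) and Klra6 (0.118). Of 20 T cell receptor beta V segments 12 were higher between SiaHi_PD1pos and SiaHi_PD1neg (median 1.96, and 0.07 under T cell core scaling), and of 53 alpha V segments 18 were higher (1.73, turning to -0.28). Between SiaLo_PD1pos and SiaHi_PD1pos 1 beta segment was lower, Trbv19, at 13.9 against 45.8 CPM, with an adjusted p of up to 0.125 without SiaHi_PD1pos replicate 1 or 3 or SiaLo_PD1pos replicate 2 or 3 and of 0.0511 in the 6 libraries. Of 30 histone genes 6 were higher and 3 lower between SiaHi_PD1pos and SiaHi_PD1neg (0.66, turning to -1.24).

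Of 15 genes of plasmacytoid dendritic cells chosen after their values were seen, 15 were lower in SiaHi_PD1pos than in SiaHi_PD1neg (median log2 -5.44). Siglech was at 888.5 CPM in SiaHi_PD1neg, 15.02 in SiaHi_PD1pos and 2.63 in SiaLo_PD1pos, Ccr9 at 565.8, 10.8 and 2.01, and Spib at 469.5, 10.8 and 2.19. The low genes Klk1, Dntt and Cd300c belong to the same set.

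The tests that follow, apart from the splits of the libraries, were chosen only after the data were seen, since the test of the exhaustion genes rests on T cell core scaling. T cell core transcripts had a median of 1.97 on the log2 scale between SiaHi_PD1pos and SiaHi_PD1neg. RNA of dendritic and melanoma cells in the SiaHi_PD1neg libraries could lower them. The labels state a CD8 gate, but RNA marking such cells was present in SiaHi_PD1neg, with Siglech at 888.5 CPM and Tyrp1 at 2441 CPM. Cd3e was at 61.2 CPM there. Whether that RNA came from cells that passed the gate was not tested, nor how much of the T cell core difference it makes up. The higher of the medians of both marker lists was -2.27 (Cd74 at 6368 against 1377 CPM, Tyrp1 at 2441 against 312.8 CPM), but this had been seen before the prediction was written and tests nothing further. If a lower T cell share alone raised every other cell type alike, 5 marker lists would move together, but their medians spanned 1.65, from -2.68 for melanoma to -1.04 for macrophages. More T cell receptor transcripts in each activated cell remain possible and were not tested, and a second sort on CD3, with a gate against CD11c, MHC class II and B220, would remove the other source.

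Higher cell division and exhaustion genes in SiaHi_PD1pos than in SiaHi_PD1neg could come from the same lower share of T cell RNA. Relative to T cell core transcripts the median of 60 cell cycle genes was -0.174, and that of the 18 exhaustion genes called higher was -0.125. That scaling lowers the median of all genes to -1.87, so nearly any list with a smaller rise would turn, and these values do not test the explanation, which stays open. Of those 18, 6 were still called higher and 5 were called lower on this scale.

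Lower naive, memory and stem-like genes in SiaLo_PD1pos than in SiaHi_PD1pos might come from dendritic cell RNA in SiaHi_PD1pos, where Cd74 was at 1377 against 684.1 CPM. If dendritic cells carried these genes at the SiaHi_PD1neg level, scaled by Cd74 (10.9% of that level), they would allow a median share of 0.248 of the differences, below 0.5 in 10 of 13 genes (Dapl1 0.0219, Slamf6 0.0566, Tcf7 0.136), while Klf2 and Il7r had a lowest share of 0.728. That profile was assumed and not measured, and Ccl22 and Il12b were also lower in SiaLo_PD1pos, so dendritic cells in another state, with more Ccr7 for example, remain open as a source. CD4 T cells, marked by Cd4 and Foxp3 (20.1 against 2.00 CPM), should have been removed by the same gate. Any that passed would lower Cd8b1 per Cd3e in SiaHi_PD1pos. That ratio was higher there than in SiaLo_PD1pos, by 0.139 on the log2 scale (SE 0.0852), under the 3 SE set for a decision. A small share of CD4 T cells could move the ratio by less than its SE, so they stay open as a source. A further gate against CD4 and MHC class II in the sort would remove both sources.

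When the 6 libraries of a comparison were split into 3 and 3 in every way, 1 of the 10 splits, the real one, gave 214 calls between SiaLo_PD1pos and SiaHi_PD1pos, 6155 between SiaHi_PD1pos and SiaHi_PD1neg and 6029 between SiaLo_PD1pos and SiaHi_PD1neg, and the highest other split gave 0. With 10 splits the share cannot fall under 0.05.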
